A study of Bifidobacterium breve UCC2003 with 5 samples.

How the data were processed

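Total RNA of Bifidobacterium breve UCC2003 and its Bbr_0838 mutant was measured on 5 two-colour arrays lying on 3 slides, with 10807 spots each, 544 of them controls. Per the file headers, scans were extracted with Agilent Feature Extraction 9.5.1.1. Each file holds the mean spot intensity and the median local background intensity per channel, not background corrected, together with processed intensity values and quality flags, per the file headers. The files also hold a log10 ratio of Cy5 over Cy3 that the software made after its own background subtraction, detrending and dye normalization, per the file headers. The value table that the authors deposited is on the log10 scale too. Its columns matched that log10 ratio on all 10807 spots to within 8.48e-05 once the sign of the 2 dye-swapped arrays was turned. By the labels its direction is therefore treated over water, or mutant over wild type. The column medians were 0.00 and -0.0203 for the arrays labelled 0.1% replicate 1 and 2, -0.000724 and 0.00 for 0.06% replicate 1 and 2, and -0.00644 for the strain array. Scale and centring are settled by that match. Direction is settled only as far as the labels hold, and Bbr_0838 went against those of 2 arrays, as given below. What was done before scanning beyond growth, exposure and labelling is not given in the sources used here.

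Groups, doses and dye orientation were taken from the labels, and replicate numbers are only names in order of deposition. The labels call the second array of each dose a dye swap and do not say whether it held separate cultures. If the RNA was shared, p-values measure only the spread between hybridizations. The labels were kept in every fit, including those of the 2 arrays that Bbr_0838 went against, and no array was moved to another group.

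From the mean and background intensities, background was corrected by normexp with an offset of 50, and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as non-uniform or population outliers were left out, between 5 and 437 per array, and saturated spots were kept. Spots of a probe were averaged. A probe was kept if well above background in at least 2 of the 10 channel readings, which left 5634 of 5664 probes. The log2 ratios of a target's kept probes, 3 at most, were averaged, and 1884 of 1888 targets had a value on all arrays. Besides locus tags these included 20 tRNA targets, with plasmid, spike and other targets. Plasmid and spike targets were well above background in 16.4% and 17.5% of readings, against 96.0% for locus tags. Of these, 13 plasmid and 6 spike targets entered the normalization and the tests, so counts out of 1884 genes below include them.

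The 4 dose arrays were fitted together with lmFit and eBayes, with 1 coefficient per dose and their difference as a contrast, and the Benjamini-Hochberg adjusted p had to be under 0.05. The strain array had no test, and genes past 2-fold were counted. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Only 1 list fixed in advance could be tested, so its adjusted p equals camera's own and was not adjusted over the 3 contrasts. On single arrays a list's median was placed among 10000 random lists matched on mean signal in 10 bins. The shared-control value came from 200 simulated sets. The fit was tested on 20 simulated sets of 1884 genes with 200 changed genes and the fitted prior spread, for the comparison at 0.1%. Each set gave both arrays at 0.1% the same true change, and all arrays the same spread per gene. The real arrays at 0.1% differed widely, so the shares below need not hold for the real data. With all 4 arrays the fit recovered 6.20% of genes changed 2-fold, 65.3% of those changed 4-fold and 92.6% of those changed 16-fold. Of its calls, 4.86% were false. Without the array labelled 0.1% replicate 1 these shares were 17.9%, 88.2% and 99.7%, and 6.62% of calls were false.

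Design, alternatives, gene lists and the naming rule were fixed before the data were examined. The rule took Bbr_0838 and 2 genes on each side of it, 9 fixed locus tags, the genes with the largest rise and fall of the same sign on both arrays of a dose, those with the smallest p for the dose difference, and the highest and lowest on the strain array with at least 2 kept probes, 75% of them sharing the sign. The files pair no locus tag with a gene name or product, and 0 of the locus tags matched the reference table of 2016 genes, which describes another strain. Beyond the fixed tags and the neighbours, at most 2 higher and 2 lower locus tags are therefore named per comparison. Of 21 planned gene lists, 20 depended on product names and had 0 members, so only the transporter candidates were tested. The bile salt hydrolase gene could not be named either.

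Alternatives were no background subtraction, Agilent's log ratio, the authors' table, median centring, 2 other filters on dim probes, the median over probes, a dye term, a trended and robust prior, a size threshold, other list tests and leaving out each dose array. Combinations of a left-out array with other normalizations, and a dye correction from the 0.06% pair, were added after the data were seen. Signal over background was the only depth the arrays offered.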

Results

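The transcriptome of a Bbr_0838 mutant of Bifidobacterium breve UCC2003, a gut bacterium, was compared on 5 two-colour oligonucleotide arrays. The series title describes the product of the disrupted gene as a membrane protein induced by bile. Cells were grown to an optical density of 0.5 and exposed for 1 h to cholic acid, a bile acid, or to the same volume of water. By their labels, 2 arrays with swapped dyes compared the mutant at 0.1% cholic acid with the mutant in water, 2 did so at 0.06%, and 1 array compared the mutant with the wild type, both at 0.1%. That last array is called the strain array here. One protocol of the array labelled 0.1% replicate 1 gives the dose as 0.15%, against 0.1% in its title. Ratios are treated over water, or mutant over wild type, on the log2 scale for 1884 array targets, of which 1842 were chromosomal locus tags. Between 8225 and 10167 of the 10263 spots per channel were well above background, the fewest in Cy5 of the array labelled 0.1% replicate 1. The median background-subtracted signal in that channel was 170, against 286 to 1180 in the 8 channels of the other arrays. The number of arrays limits the precision of every comparison.

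Bbr_0838 was measured first, since its ratio checks the labels. Mutant RNA is named in both channels of the 4 dose arrays, and in 1 channel only of the strain array. The gene was at -3.67 ± 0.31 (SD over 3 probes) on the array labelled 0.1% replicate 1, a 12.7-fold lower ratio and the lowest of the 1884 targets. It was at -4.36 there with Agilent's log ratio and at -3.84 after median centring. The next lowest target on that array was at -0.69. On the strain array Bbr_0838 was at 0.01 ± 0.21 (SD over 3 probes). It was at 0.00 on 0.1% replicate 2, at 0.65 on 0.06% replicate 1 and at -0.07 on 0.06% replicate 2. On 0.1% replicate 2, 2 of its 3 probes were not well above background in Cy3, so the ratio there says little. The mean Cy3 signals of its probes on the array labelled 0.1% replicate 1 were 4073, 27535 and 5990, against 112 to 691 in Cy5. In the 8 channels of the other arrays they lay between 60 and 1222. All 3 probes were lower on the array labelled 0.1% replicate 1, by 10.6-fold to 16.1-fold, and the labels do not say which part of the gene was removed. The gene went against the labels of 2 arrays, the one labelled 0.1% replicate 1 and the strain array, and every direction drawn from either array carries that limit.

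**Figure D1:**
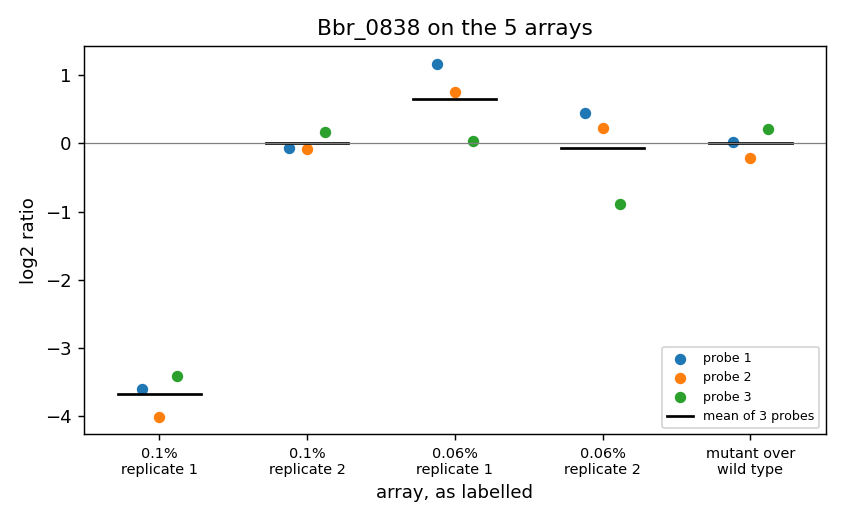
Log2 ratio of Bbr_0838 on each array, with 1 point per probe and a bar at the mean of the 3 probes. The gene is at -3.67 on the array labelled 0.1% replicate 1 and between -0.07 and 0.65 on the other 4 arrays.

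The comparison at 0.1% asks which genes of the mutant respond to the higher dose of cholic acid. The 2 arrays carrying that label differed widely. On 0.1% replicate 2, 366 genes were at least 2-fold higher and 184 at least 2-fold lower in treated cells, whereas on the array labelled 0.1% replicate 1 these counts were 8 and 1. No gene was past 2-fold in the same direction on both, and 7 were past it in opposite directions. Among genes with the same sign on both arrays, Bbr_0106 had the highest mean, 3.36 ± 3.65 (SD, n = 2), from 0.78 and 5.94. Bbr_1417 had a mean of 3.31 ± 4.18, from 0.36 and 6.27. The lowest means belonged to Bbr_1534, at -1.76 ± 2.02, and to Bbr_1792, at -1.51 ± 1.66. None of these 4 genes passed the test, each with an adjusted p of 0.585 from limma. In the limma fit over the 4 dose arrays, 0 of 1884 genes passed at 0.1%, and 18 had an unadjusted p under 0.05. Without the array labelled 0.1% replicate 1, 403 genes passed, 290 higher and 113 lower, with the remaining array assumed to vary like the pair at 0.06%. In that fit Bbr_1417 rose by 6.27 (SE 0.27, adjusted p = 0.00293) and Bbr_0106 by 5.94 (SE 0.38, adjusted p = 0.00311). Bbr_1534 fell by 3.19 (adjusted p = 0.0124) and Bbr_1792 fell by 2.68 (adjusted p = 0.00738). The split between higher and lower depended on the scaling, with 291 higher and 281 lower from Agilent's log ratio in the same fit.

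**Figure D2:**
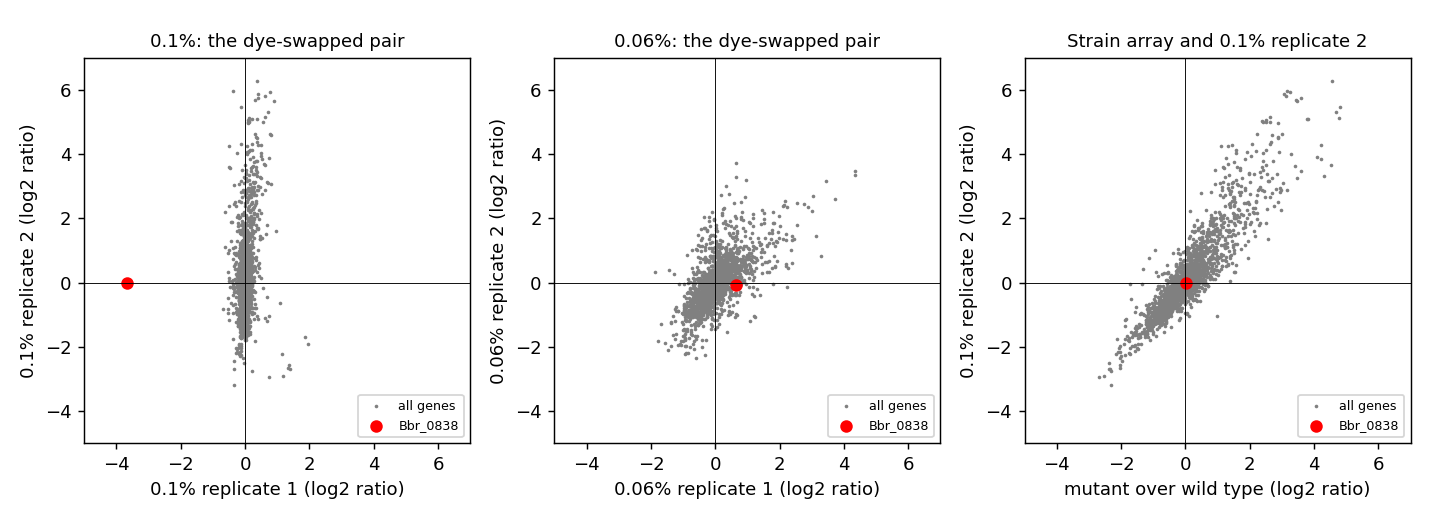
Log2 ratios of 1884 targets on 3 pairs of arrays, with Bbr_0838 in red and both axes on the same scale. The pair at 0.1% correlates across genes at r = 0.246, the pair at 0.06% at r = 0.644, and the strain array with 0.1% replicate 2 at r = 0.902.

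At the lower dose of 0.06% the pair of arrays was more alike. There were 65 targets at least 2-fold higher on both arrays and 21 at least 2-fold lower on both, against 3 past 2-fold in opposite directions. Bbr_0106 had the highest mean, 3.90 ± 0.61 (SD, n = 2), a 14.9-fold ratio, followed by Bbr_0107 at 3.86 ± 0.70. Bbr_0371 had the lowest mean, -1.80 ± 0.04, followed by Bbr_0863 at -1.78 ± 0.44. In the limma fit over all 4 dose arrays, 0 genes passed at 0.06% and 212 had an unadjusted p under 0.05, with an adjusted p of 0.430 for each of these 4 genes. The spread in that fit takes in the gap between the unlike arrays at 0.1%. Without the array labelled 0.1% replicate 1, 59 genes passed, 48 higher and 11 lower. The same count of 59 came from leaving out 0.1% replicate 2 instead, since the spread was then taken from the 0.06% pair alone. With the array labelled 0.1% replicate 1 left out, Bbr_0106 and Bbr_0107 rose (adjusted p = 0.0172 for both) and Bbr_0371 and Bbr_0863 fell (adjusted p = 0.0225 and 0.0404). After median centring in place of loess, with that array left out, 0 genes passed at 0.06%, and with Agilent's log ratio 19 were higher and 2 lower. The split of targets past 2-fold depended on the scaling as well. It was 124 higher and 31 lower on replicate 1 and 181 and 117 on replicate 2, against 144 and 82, and 195 and 161, with Agilent's log ratio. After median centring it was 116 and 61, and 171 and 161.

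The genes beside Bbr_0838 were followed too. Bbr_0836 was at 1.40 ± 0.31 (SD, n = 2) at 0.06%, at 3.57 on 0.1% replicate 2 and at -0.46 on the array labelled 0.1% replicate 1. It did not pass in the fit over all 4 arrays, and rose at both doses without the latter array (adjusted p = 0.00425 at 0.1% and 0.0456 at 0.06%). Means at 0.06% were 0.54 ± 0.78 for Bbr_0837, 0.76 ± 0.22 for Bbr_0839 and -0.41 ± 0.27 for Bbr_0840, and none of these 3 passed in either fit.

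The doses were then set against each other. Of the 59 genes that passed at 0.06% without the array labelled 0.1% replicate 1, 57 had the same sign on 0.1% replicate 2, and 49 had a larger size there. Their median size was 1.71 at 0.06%, 3.26 on 0.1% replicate 2 and 0.23 on the array labelled 0.1% replicate 1. In that fit 46 genes rose at both doses and 4 fell at both, against 7.39 and 0.66 for independent lists, and 0 moved in opposite directions. Both lists were called with the same spread per gene, from 1 residual degree of freedom of the 0.06% pair, which alone can raise the overlap above that of independent lists. Across genes, which are not independent replicates, the mean changes at the 2 doses correlated at r = 0.697 (Spearman's rho 0.625), with a covariance of 0.30. The covariance with the mean of 0.06% was 0.58 for 0.1% replicate 2 alone. For the array labelled 0.1% replicate 1 it was 0.025 with 0.06% replicate 1 and 0.0080 with 0.06% replicate 2. Between single arrays of the 2 doses, r was highest, at 0.702, for 0.1% replicate 2 and 0.06% replicate 2, which shared a slide and a dye orientation. It was lowest, at 0.050, for the array labelled 0.1% replicate 1 and 0.06% replicate 2. The labels do not say whether the water controls were shared. After scaling between arrays, the water channels of 0.1% replicate 2 and 0.06% replicate 2 correlated at 0.995, and those of the 0.06% pair at 0.971. The first 2 channels share a slide and a dye, so this cannot tell shared RNA from a shared slide. Simulated sets had fully shared controls, no effect and equal noise in control and treated RNA. Over 200 sets the mean r was 0.500 and the covariance 0.0377. That r follows from the equal noise by construction, so it is no benchmark for the observed r. The simulated covariance is that of single arrays, whereas 0.30 is that of means over arrays. Part of the correlation and overlap may still come from shared controls. No gene passed the limma test of the difference between doses, and 34 had an unadjusted p under 0.05. Of the genes higher at 0.1% than at 0.06%, Bbr_1660 and Bbr_0408 had the smallest p-values, with differences of 1.68 ± 0.28 and 1.22 ± 0.26 (SE). Of those lower at 0.1%, Bbr_0479 and Bbr_1581 had the smallest, with differences of -1.68 ± 0.33 and -1.34 ± 0.28. Each had an adjusted p of 0.969 from limma. Bbr_1660, Bbr_0408 and Bbr_0479 changed little at 0.1%, with means of -0.03, -0.09 and -0.22. Their means at 0.06% were -1.71, -1.31 and 1.46. Bbr_1581 had means of -0.76 at 0.1% and 0.58 at 0.06%. Without the array labelled 0.1% replicate 1, 34 genes passed, all 34 higher at 0.1%, and 0 passed under Agilent's log ratio or median centring. Within the shared slide, 295 genes were at least 2-fold higher at 0.1% than at 0.06% and 93 at least 2-fold lower, with no test.

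A group of 9 locus tags was fixed in advance as transporter candidates, Bbr_0838 among them. The other 8 were higher in treated cells on 0.1% replicate 2, from 2.51 for Bbr_1756 to 4.97 for Bbr_0406. On the array labelled 0.1% replicate 1 the same 8 lay between -0.05 and 0.24. At 0.06% the highest means were those of Bbr_1804, at 1.85 ± 0.56 (SD, n = 2), and Bbr_1805, at 1.84 ± 0.46. In the limma fit over all 4 dose arrays, 0 of the 9 passed at either dose, also when adjusted over the list alone. Without the array labelled 0.1% replicate 1, 8 of the 9 rose at 0.1% and 2 rose at 0.06%, and the counts adjusted over the list alone were 8 and 4. Bbr_0838 itself did not pass there at 0.1%, where its ratio rests on the dim probes of 0.1% replicate 2. The median of the 9 was 1.48 at 0.1% and 0.73 at 0.06%, against -0.0042 and 0.026 for all other genes (camera with a preset correlation, adjusted p = 0.00231 and 0.0353). Both calls were lost with the correlation estimated from the residuals (adjusted p = 0.393 at 0.1% and adjusted p = 0.533 at 0.06% with an estimated correlation). That estimate, 0.956, rests on 2 residual degrees of freedom, 1 of them the gap between the unlike arrays at 0.1%. It cannot separate that gap from correlation between genes. The call at 0.1% was also lost without 0.1% replicate 2 (median 0.055, adjusted p = 0.0938), and the call at 0.06% without 0.06% replicate 2 (median 0.65, adjusted p = 0.251). The difference in shift between doses did not pass over all 4 arrays (median difference 1.06, adjusted p = 0.517 from camera). It passed in opposite directions depending on which array at 0.1% was left out, at 2.49 without the array labelled 0.1% replicate 1 (adjusted p = 0.000145) and at -0.88 without 0.1% replicate 2 (adjusted p = 4.84e-05). The fit behind the first of these calls has 1 residual degree of freedom, so the residuals of any 2 genes are perfectly correlated or perfectly opposed. An estimated correlation therefore cannot decide that call, and it was not run for the second. The tags were recalled from published work that may include these samples, so their direction is not independent evidence, and the files give no product for them.

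**Figure D3:**
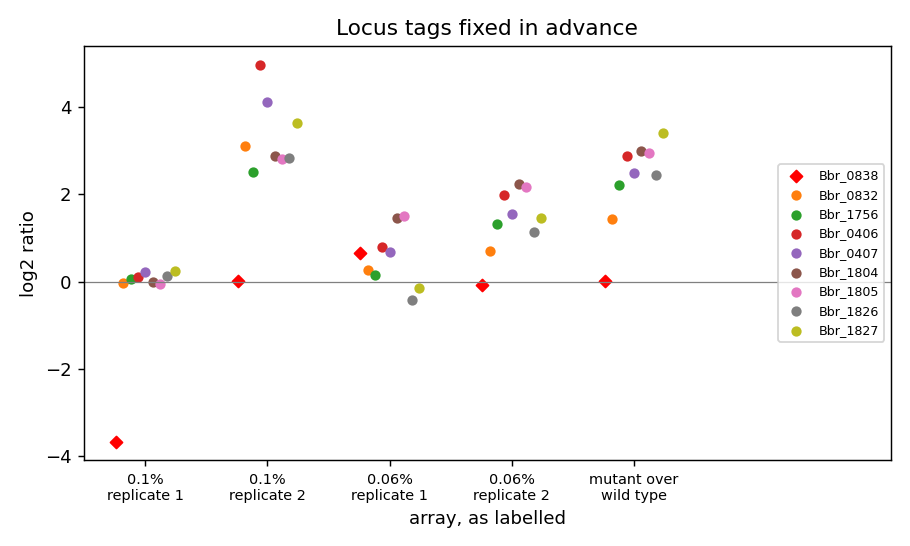
Log2 ratios of the 9 locus tags fixed in advance on each array, with 1 point per gene and Bbr_0838 as a red diamond. The other 8 lie between 2.51 and 4.97 on 0.1% replicate 2, and between -0.05 and 0.24 on the array labelled 0.1% replicate 1.

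The strain comparison asks how the mutant and the wild type differ under 0.1% cholic acid. It rests on 1 array, which has no replicate and no dye swap, so it has no test and is open to dye bias. Bbr_0838 was at 0.01 there, against the label, so the values below may not be a strain difference. On the array so labelled, 265 genes were at least 2-fold higher in the channel named as mutant and 146 at least 2-fold lower. These counts were 299 and 258 with Agilent's log ratio, and 243 and 212 after median centring. With the dye effect of the 4 dose arrays subtracted they were 360 and 261, and with that of the 0.06% pair alone 300 and 213. The first estimate takes in the gap between the 2 arrays at 0.1%, which need not be a dye effect. The highest ratios were those of Bbr_1183, at 4.80 ± 0.03 (SD over 3 probes), and Bbr_1781, at 4.78 ± 0.05. The lowest were those of Bbr_0435, at -2.69 ± 0.09, and Bbr_0436, at -2.54 ± 0.46. These SDs cover the probes of 1 array only. Over the alternatives the 4 ratios ranged from 4.77 to 6.78, 4.59 to 6.55, -3.93 to -2.59 and -3.90 to -2.01, with the largest sizes after the dye effect of the 4 dose arrays was subtracted. All 4 genes had the same sign on 0.1% replicate 2, at 5.47, 5.11, -2.93 and -2.90. On the array labelled 0.1% replicate 1 they were at -0.11, 0.11, 0.74 and 1.19, so 3 had the opposite sign. The 9 locus tags fixed in advance had a median of 2.50, at the 100th percentile of 10000 random lists matched on signal. Bbr_0838 had the lowest ratio among the 9. The random lists drew genes singly. Among the tags Bbr_0406 and Bbr_0407, Bbr_1804 and Bbr_1805, and Bbr_1826 and Bbr_1827 are neighbours, so the rank may be too extreme. Across genes the strain array correlated with 0.1% replicate 2 at r = 0.902 and with 0.06% replicate 2 at 0.762. It correlated with 0.06% replicate 1 at 0.486 and with the array labelled 0.1% replicate 1 at 0.25. On both the strain array and 0.1% replicate 2, 234 genes were at least 2-fold higher and 114 at least 2-fold lower, with 0 in opposite directions.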

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

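The combinations of a left-out array with another normalization, and the dye correction from the 0.06% pair alone, were chosen after seeing the data. With all 4 dose arrays, 0 genes passed at either dose or for their difference under every normalization, filter, probe summary, dye term and prior that was run. Each of these fits took the gap between the unlike arrays at 0.1% into the spread of every gene, at 0.06% too. The counts of 0 are therefore not separate evidence that no gene changed. Leaving out each dose array in turn gave 0 to 403 genes at 0.1%, 0 to 59 at 0.06% and 0 to 34 for the difference. The highest counts came without 0.1% replicate 1, and 59 at 0.06% also without 0.1% replicate 2, where the spread came from the 0.06% pair alone. With 0.1% replicate 1 left out, the counts at 0.1%, at 0.06% and for the difference were 335, 27 and 16 with no background subtraction, 572, 21 and 0 with Agilent's log ratio, and 480, 0 and 0 with median centring. The cause was not tested. The correlation between doses ranged from 0.12 without 0.1% replicate 2 to 0.71 without 0.1% replicate 1.

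The strain array's count of 411 became 621 with the dye effect of the 4 dose arrays subtracted, and 513 with that of the 0.06% pair alone. The first estimate takes in the gap between the 2 arrays at 0.1%, which need not be a dye effect. It was 173 at 3-fold, by the stricter threshold itself. The median of the 9 fixed tags there, 2.50, was 2.60 with Agilent's log ratio and with the authors' table, 2.18 with median centring and 3.69 with the dye effect subtracted. At 0.1% and 0.06% the medians of 1.48 and 0.73 no longer passed with a correlation estimated from 2 residual degrees of freedom. The fry test, which sets the list against no change and not against other genes, did not pass either (adjusted p = 0.383 and 0.556 by fry). The median of 0.73 also missed with the strict filter on dim probes (adjusted p = 0.0521). Leaving out each array gave medians of 0.055 to 2.88 at 0.1%, 0.65 to 1.46 at 0.06% and -0.88 to 2.49 for the difference. The call at 0.1% was lost without 0.1% replicate 2 (adjusted p = 0.0938) and the call at 0.06% without 0.06% replicate 2 (adjusted p = 0.251). The difference reversed without 0.1% replicate 2, and passed in opposite directions when one or the other array at 0.1% was left out.

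Among single genes, signs turned mostly where 1 of the 2 arrays of a dose was left out. At 0.1% the ranges were -3.67 to 0.0045 for Bbr_0838, -0.030 to 3.11 for Bbr_0832, -0.011 to 2.88 for Bbr_1804, -0.046 to 2.81 for Bbr_1805, -0.46 to 3.57 for Bbr_0836 and -0.13 to 0.17 for Bbr_0840. At 0.06% they were -0.073 to 0.65 for Bbr_0838, -0.42 to 1.13 for Bbr_1826, -0.15 to 1.46 for Bbr_1827 and -0.0073 to 1.097 for Bbr_0837. The strict filter turned Bbr_0838 at 0.06% to -0.43. None of these genes passed at that dose in the fit over all 4 arrays. Without 0.1% replicate 1, Bbr_0832, Bbr_1804, Bbr_1805 and Bbr_0836 passed at 0.1% (adjusted p = 0.00508, 0.0104, 0.00894 and 0.00425). Of the other alternative values of named genes, 530 stayed on their side of the threshold or, on the strain array, within the SD of the probes, 27 newly passed in the same direction, and 59 on the strain array moved by more than that SD. No named gene passed in the fit over all 4 arrays, so for the doses staying on that side means still not passing. Agilent's log ratio and the authors' table were counted separately, though their results differed by at most 4.97e-06. Slide could not be fitted as a random block, because 4 arrays on 3 slides with 2 coefficients left no estimate of the correlation. The replicate numbers are names only, but they coincide with dye orientation, so the dye term is also a block on the number. It left 0 genes passing and changed no call on the list. Cy5 of the array labelled 0.1% replicate 1 had the lowest median background-subtracted signal of the 10 channels, 170.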

Other observations

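Locus tags past 2-fold lay in runs of consecutive numbers more than in shuffled orders, and membership of a run does not mean that a gene passed a test. Of 65 locus tags at least 2-fold higher on both arrays at 0.06%, 26 lay in 8 runs of 3 or more consecutive tags, against a mean of 0.23 genes in 1000 shuffled orders. The longest runs, Bbr_0106 to Bbr_0109 and Bbr_1891 to Bbr_1894, held 4 genes each and were chosen after their values were seen. The first had mean log2 ratios of 3.82 and 2.95 on the 2 arrays at 0.06%, 5.20 on 0.1% replicate 2 and 0.81 on the array labelled 0.1% replicate 1. Of 20 lower on both, 3 lay in 1 run, against a mean of 0.003. On 0.1% replicate 2, 171 of 356 higher tags lay in 37 runs, against a shuffled mean of 32.2, and 69 of 184 lower tags lay in 14 runs, against 4.76. The 20 tRNA targets, a group chosen after the data were seen, had a median of 0.80 on 0.1% replicate 2, with 18 of 20 above 0, and of 0.43 on the strain array. Their medians were 0.04 and -0.37 on the 2 arrays at 0.06%. On the array labelled 0.1% replicate 1 the median was -0.055, with 7 of 20 above 0.

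The tests of the label exchange, the higher dose, the dye effect and the shuffled order were chosen after the values were seen, and the other tests below before their own results were seen. The array labelled 0.1% replicate 1 differed from its dye swap (r = 0.246), with Bbr_0838 as its lowest target. Weak hybridization of dim spots as the whole cause is argued against by the 471 genes brightest on that array, where its slope on 0.1% replicate 2 was 0.068 ± 0.007 (SE). If changes grow with dose and the array holds treated over water as labelled, a higher dose would give a slope of at least 1. The slope over all genes was 0.040 ± 0.004, with an SE over genes that are not independent. Neither assumption was tested, so the slope cannot decide on a higher dose. A candidate explanation that stays open is an exchange of labels with the strain array, which lay on the same slide, correlated with 0.1% replicate 2 at r = 0.902 and lacked a lower Bbr_0838 ratio (0.01). By the labels both arrays hold treated mutant RNA, so a positive r is expected without an exchange, and its size without one was not simulated for this pair. After scaling between arrays, channels were correlated with the water channel and the treated channel of 0.1% replicate 2. Cy3 of the strain array, labelled as treated wild type, gave 0.979 and 0.831, so it was nearer the water channel. Cy5 of the strain array, labelled as treated mutant, gave 0.832 and 0.965. Cy3 of the array labelled 0.1% replicate 1, labelled as water, gave 0.826 and 0.960. Cy5 of that array, labelled as treated, gave 0.815 and 0.966. Both its channels were thus nearer the treated channel, which goes against its label of water. An exchange would give each of these positions, and the high Cy3 signals of Bbr_0838 on that array. No test set an exchange against other labelling errors. With the water channels of replicates 1 and 2 at the lower dose, Cy3 of the strain array correlated at 0.969 and 0.981. With the treated channels there it gave 0.914 and 0.933. Cy3 of the array labelled 0.1% replicate 1 gave 0.851 and 0.829 with water there, and 0.881 and 0.938 with treated. These Cy3 positions thus did not rest on 0.1% replicate 2 alone, though water RNA may have been shared between arrays. The values of the strain array and of the array labelled 0.1% replicate 1 each rest on 1 array.

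On the array labelled 0.1% replicate 1 the 8 genes from Bbr_0434 to Bbr_0441, singled out after their values were seen, had a mean of 1.17 ± 0.51 (SD over 8 genes) in Cy5 over Cy3. On 0.1% replicate 2 and the strain array their mean ratios were -2.58 and -2.19. A dye effect of these genes may account for part of the first value, since their mean Cy5 over Cy3 offset in the 0.06% pair was 0.51 ± 0.13 (SD over 8 genes). That offset fell short of 1.17 by slightly more than both SDs added. The SDs are over neighbouring genes of 1 run and not over arrays, so they cannot decide whether a dye effect is the whole cause. Any other difference between the 2 arrays at 0.06% would also enter the offset. A difference in treatment or in strain between the channels was not tested and stays open.

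For the runs of neighbouring genes, chance order is argued against by a permutation p of 0.001, the smallest that 1000 shuffles can give, and of 0.002 for the single lower run at 0.06%. A trend across the slide surface is argued against by the layout, since probes of adjacent tags lay 1.00 times as far apart as random pairs. A broad trend along the chromosome as the whole cause is argued against as well. The correlation of adjacent tags at 0.06% was 0.476, and 0.447 after a smooth curve was subtracted. No biological explanation was tested, because the design gives none and the files do not give strands or operons.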
